A study of Mus musculus with 2 samples.

How the data were processed

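Slide-seq libraries of ovary sections from C57BL6/J mice were analysed, 1 from a young female (2 months) and 1 from an old female (about 14 months). Per the labels' protocols, 4 cryosections of 10 µm came from 2 females per age cohort and were chosen to show several oocytes; the other sections were not analysed here. The deposited tables give whole-number counts per gene and bead with the position of each bead on the array. Per the submitters' processing notes the genome build was mm10; the aligner, the counting program, the annotation and whether counts are molecules or reads are not given in the sources used here. The deposited tables list only beads with at least 10 counts and genes with at least 1 count, so a gene listed for 1 section and not for the other was taken as 0 there. Bead positions carry no stated length unit, so distances are in bead spacings, the median distance from a bead to its nearest neighbour. Of the 22204 gene names in either table, 18804 matched the names or synonyms of the GRCm38.p6 RefSeq table.

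The array held 77892 beads with a position in the young and 83379 in the old section, of which 21403 and 10267 had counts. A rule set beforehand would have kept only beads over tissue, those above an Otsu threshold of the mean count of the 30 nearest beads, if the classes on either side differed at least 4-fold in mean. They differed 2.94-fold in the young and 2.60-fold in the old section, so all beads with counts were kept, which made an analysis of all beads the same. Mitochondrial genes took 1.79% of counts in the young and 1.37% in the old section. The noncoding genes Neat1 and Mir6236 took 0.0517% and 0.124% in the young section and 0.266% and 0.484% in the old.

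Counts were summed over all beads of a section and scaled to a common total per section (CPM). The old/young ratio was given with an exact conditional binomial (Clopper-Pearson) 95% interval, and levels with exact Poisson intervals, all for counting error only. A gene with 0 counts in a section was set against a floor of 3 counts there as a bound. No test between ages was made because each age had 1 library. The 36 gene lists were fixed before the data were examined. For each list, members with at least 20 counts in 1 section were counted as higher or lower by a size of 1.5-fold, without a test, and the list's median ratio was placed among 10000 random lists matched on expression in 20 bins, as a description. Genes were named by a rule of size fixed at the same time: among genes with at least 50 counts and 20 CPM in 1 section, leaving out mitochondrial, ribosomal protein and predicted or clone-named genes, the 12 highest and 12 lowest ratios, plus up to 3 highest, 3 lowest and the 2 most abundant members of each list described. How clone-like names were recognised was settled after the ranking was seen, when 1 such gene was left out and Fbxw16 took its place.

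Regions were made from square bins of 5 bead spacings with at least 500 counts, 1338 in the young and 895 in the old section. Both sections were clustered together, without integration, on log values per 10000 counts of 2000 variable genes, with 20 principal components, 15 neighbours and Leiden resolution 1.0 (scanpy 1.11.5, python-igraph 0.11.9). Regions are called by their 3 leading genes and were compared only with at least 20 bins in each section. Spatial pattern was described by variance over mean and by Moran's I over the 8 adjoining bins after thinning each bin to 500 counts. Oocyte foci were groups of adjoining bins with at least 10 oocyte-list counts that made up at least 1% of the bin. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.

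The ratio step was tested on simulated counts for genes drawn at the mean level of the sections, of which 8125 lay at 20 CPM or more. The intervals held the true ratio for 95.4% of genes. The counts were drawn under the counting model that the intervals assume. This value therefore checks the calculation only, and holds no spread between animals or sections. Of 50 genes each simulated 1.5-fold higher or lower, 96% and 76% had an interval on the right side of 1, and of 50 each simulated 3-fold higher or lower, 100% did. The focus step found 4 of 4 foci placed far apart in a simulated section, so the merging of neighbouring foci was not tested.

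Alternatives set beforehand were beads with at least 200 counts, totals without mitochondrial, ribosomal protein and haemoglobin genes, a trimmed-mean scaling, equal weight per bin, lists without their most abundant member, leaving out each quadrant of each section in turn, other count minimums for naming, other bin sizes, resolutions and thinning depths, and other focus thresholds. Restriction to densely covered parts of the array, and the comparison of bins ranked by an anchor list within a section, were added after seeing the data. So were the foamy or giant macrophage list without Spp1 and without Lgals3, and the choice of the lists whose members are described in most detail.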

Results

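Gene expression was mapped across 1 ovary section from a young C57BL6/J female mouse (2 months, replicate 3) and 1 ovary section from an old female (about 14 months, replicate 1) by Slide-seq, in which a tissue section is laid on an array of barcoded beads whose positions are known. The study's title names ovarian inflammaging, the inflammation that accompanies reproductive ageing, so the comparison asks how the old section differs from the young one in follicle, luteal, stromal and immune genes. The young section held 5158314 counts on 21403 beads, with a median of 153 counts and 134 genes per bead. The old section held 2348768 counts on 10267 beads, with a median of 125 counts and 111 genes per bead. Each age is represented by 1 library from 1 animal, so age, animal, section plane and library cannot be separated, no test of age was possible, and every 95% interval covers counting error only. Differences are given as the old/young ratio of CPM, the counts scaled to a common section total, where values below 1 are lower in the old section.

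Genes of growing follicles were far lower in the old section. The oocyte list, which holds zona pellucida and other egg genes, stood at 334.2 CPM against 3605 in the young section. The ratio was 0.0927 (0.0862 to 0.0996), and all 26 measured members were at least 1.5-fold lower. The granulosa list, of the somatic cells that surround the oocyte, stood at 2927 against 11036 CPM. The ratio was 0.265 (0.259 to 0.272), and 10 of 12 measured members were at least 1.5-fold lower and none higher by that size. The theca list, of the androgen-producing outer follicle layer, had a ratio of 0.252 (0.244 to 0.260). Among oocyte genes, Oosp2 had a ratio of 0.0314 (0.00078 to 0.181), Nlrp14 of 0.0327 (0.0253 to 0.0417) and Oosp3 of 0.0366 (0.00091 to 0.212). The highest members were Tle6 at 0.446, Gdf9, an oocyte growth factor, at 0.299 and Npm2 at 0.260. H1f8, an oocyte linker histone, had a ratio of 0.108. Among granulosa genes, aromatase Cyp19a1 had a ratio of 0.0205 (0.00557 to 0.0529), the activin subunit gene Inhba of 0.0420 (0.0360 to 0.0486), and Hsd17b1 of 0.149 (0.114 to 0.193). The gap junction gene Gja1 had a ratio of 0.196, while the transcription factor genes Nr5a2 and Foxl2 had ratios of 1.48 and 0.905. The theca ratio rested largely on Aldh1a1, at 0.113, and was 0.708 without it. Cyp17a1, which encodes the androgen-forming 17-alpha-hydroxylase, had a ratio of 0.0224 (0.00899 to 0.0465) on 7 old counts. Without the old section's quadrant of low x and low y the oocyte ratio was 0.0504 and the Nlrp14 ratio 0.0113. Sections were chosen by the authors to contain several oocytes, per the labels' protocols, so these values are not measures of the ovarian reserve.

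**Figure D1:**
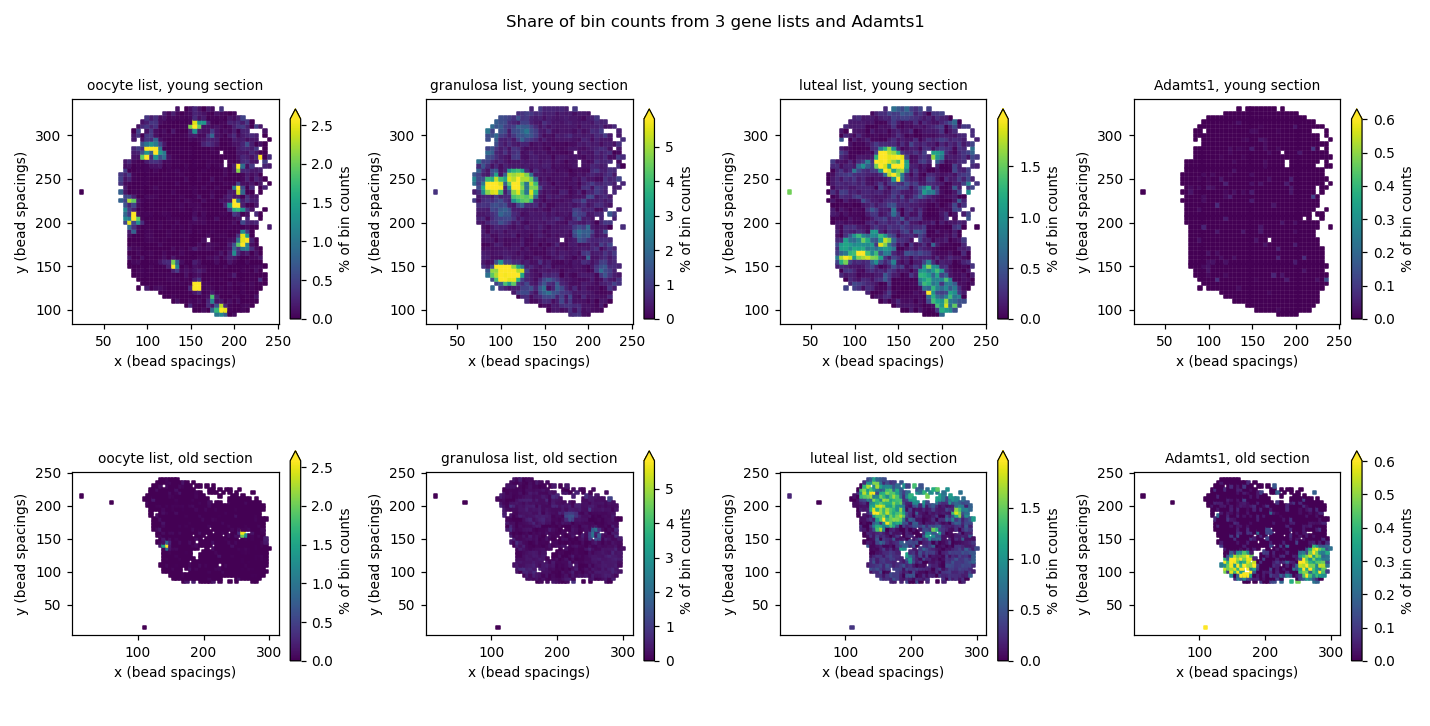
Maps of the young section (top) and the old section (bottom), x and y in bead spacings, with each square a bin of at least 500 counts coloured by the percentage of its counts from the oocyte, granulosa or luteal list or from Adamts1, on a scale shared by both sections and ending at the 99th percentile. Oocyte foci number 15 in the young and 2 in the old section, and Adamts1, at 1520 CPM in the old section against 23.5 in the young, lies in patches of the old section.

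Genes induced in follicles at ovulation had the highest ratio of the lists. The periovulatory list had 1574 CPM in the old section and 29.9 in the young, a ratio of 52.7 (44.9 to 62.3). Of its 9 members only 4 were measured, and all 4 were at least 1.5-fold higher. The others, Has2, Ptx3, Areg, Ereg and Pgr, had fewer than 20 counts in each section. Adamts1, a matrix protease induced in follicles before ovulation, supplied most of these counts, with a ratio of 64.8 (54.1 to 78.3), and the list without it had a ratio of 8.32. Tnfaip6, which stabilises the cumulus matrix, had a ratio of 8.42 (3.33 to 25.3), and Btc, an EGF-family ligand, of 7.99 (4.02 to 17.3). Ptgs2, the inducible cyclooxygenase, had 32 counts in the old section and none in the young, at least 23.4-fold higher against a floor of 3 counts in the section, with a lower 95% limit of 18.0. The 12 genes with the highest ratios by a fixed size rule included Prkg2, a cGMP-dependent kinase, at 206 (69.9 to 1007), Nts, which encodes neurotensin, at 52.7 (19.9 to 197), and the cyclooxygenase-1 gene Ptgs1 at 49.7 (34.7 to 73.7). Others were Spp1, which encodes osteopontin, at 41.1 (32.3 to 53.0), the apelin gene Apln at 37.8 (15.6 to 119) and the tissue factor gene F3 at 30.1 (21.5 to 43.2). Edn2, which encodes endothelin 2, and Myh13 had no counts in the young section, so they were at least 64.4-fold and 47.6-fold higher against the floor of 3 counts, which leaves out counting error in the old section. With it, the lower 95% limits were 51.3 and 37.6. Bhmt and Ldhd were also in the group, with ratios of 34.5 and 26.8. Without the old section's quadrant of high x and low y the periovulatory list had a ratio of 32.5, Adamts1 of 40.05, Ptgs1 of 29.9, Spp1 of 19.1 and F3 of 15.2, and Edn2 and Myh13 were at least 26.8-fold and 27.9-fold higher. Without its quadrant of low x and high y Bhmt had a ratio of 10.4, and on beads with at least 200 counts Ptgs1 had a ratio of 92.2.

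The 12 genes with the lowest ratios included Nlrp14 of the oocyte list, Cyp19a1 of the granulosa list and Cyp17a1 of the theca list, all given above. Pramef12 had a ratio of 0.0140 (0.00169 to 0.0510), Lhx8, an oocyte transcription factor gene, of 0.0146 (0.00177 to 0.0534), Fbxw18 of 0.0166 (0.00042 to 0.0943) and Oog4 of 0.0171 (0.00206 to 0.0624). Oog2 had a ratio of 0.0252 (0.00303 to 0.0926) and Astl, which encodes the egg protease ovastacin, of 0.0325 (0.00390 to 0.120). Grem1, a BMP antagonist made by granulosa and cumulus cells, had a ratio of 0.0149 (0.00306 to 0.0437), and Wipf3 and Fbxw16 had ratios of 0.0207 (0.00249 to 0.0758) and 0.0359 (0.00969 to 0.0930).

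Cholesterol synthesis genes were higher in the old section as a group, and steroid-forming genes lay on both sides of the young level. The cholesterol synthesis list had a ratio of 3.25 (3.13 to 3.37), with 12 of 15 measured members at least 1.5-fold higher and none lower by that size. Dhcr7 had a ratio of 8.60 (6.96 to 10.7), Fdps of 6.91 (5.95 to 8.06), Cyp51 of 5.30 (4.29 to 6.57), Msmo1 of 4.47 (4.15 to 4.82) and Hmgcs1 of 3.33 (3.07 to 3.61). Fdft1 had a ratio of 1.31 and Mvk of 1.45. The steroidogenesis list had a ratio of 1.43 (1.42 to 1.45), with 6 of 13 members at least 1.5-fold higher and 5 lower. Its highest members were Hsd17b7 at 12.7 (10.97 to 14.7), Star, the carrier of cholesterol into mitochondria, at 7.44 (6.91 to 8.01) and Fdxr at 3.52 (3.34 to 3.71). Its most abundant members, Hsd3b1 and Cyp11a1, had ratios of 0.932 and 2.16, and its lowest were Cyp19a1, Cyp17a1 and Hsd17b1. The luteal list, of the corpus luteum, had a ratio of 1.48 (1.45 to 1.52). Scarb1, a receptor for lipoprotein cholesterol, was at 3.12, Prlr at 1.93, Sfrp4 at 1.44, Ptgfr at 1.13, Akr1c18 at 0.868 and Onecut2 at 0.525. The luteal ratio was 0.962 without the old section's quadrant of low x and high y, so its direction depended on that part of the section.

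Matrix and epithelial lists were higher in the old section, while the summed stromal fibroblast and smooth muscle lists were near the young level with members on both sides of it. The collagen and matrix list had a ratio of 2.13 (2.09 to 2.17), with 11 of 24 members at least 1.5-fold higher and 2 lower. Its highest members were Lox, a collagen crosslinking enzyme, at 9.29 (6.75 to 13), Timp1, an inhibitor of matrix proteases, at 8.36 (7.87 to 8.88) and Sparc at 5.03 (4.83 to 5.24). In the old section Timp1 was 2.57 times higher (2.43 to 2.71) in the fifth of bins highest in Adamts1 than in the others, a contrast chosen after the data were seen. Col1a2 had a ratio of 0.722 (0.687 to 0.760), Fbn1 of 0.474 (0.387 to 0.576) and Postn of 0.359 (0.230 to 0.542). The surface epithelium list had a ratio of 4.24 (3.78 to 4.75), with the keratin genes Krt7 at 9.26 and Krt19 at 7.71, Upk1b at 6.11 and Krt8 at 1.13. A region led by Lgals7, Crip1 and C3, with Krt19, Epcam and Upk1b among its next genes, held 166 old and 4 young bins. How much epithelium each section caught cannot be told apart from a higher level within it. The stromal fibroblast list had a ratio of 0.914 (0.859 to 0.972), and of 1.11 without the young section's quadrant of high x and high y. Of its 8 measured members, 2 were at least 1.5-fold higher, among them Dpt at 3.29, and 2 lower, Tcf21 at 0.581 and Ogn at 0.439. The smooth muscle list had a ratio of 0.966 (0.927 to 1.01), with 2 of 9 members at least 1.5-fold higher, Des at 4.25 and Tpm2 at 2.27, and 4 lower, among them Myl9 at 0.554. The pericyte list had a ratio of 1.197 (1.06 to 1.35), blood endothelium of 1.44 (1.33 to 1.56), lymphatic endothelium of 0.557 (0.493 to 0.628) and red blood cell of 1.06 (0.996 to 1.13).

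**Figure D2:**
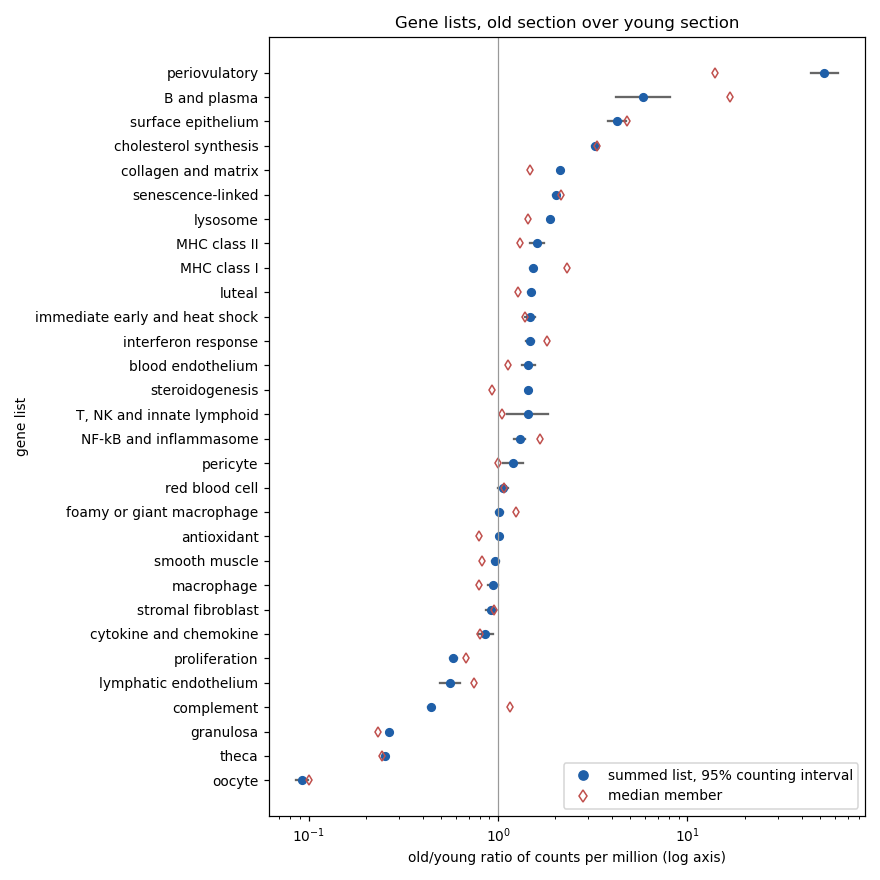
Old/young ratio of CPM on a log axis for each gene list with at least 3 measured members, with circles for the summed list, lines for its 95% counting interval and open diamonds for the median member. Ratios run from 0.0927 for the oocyte list to 52.7 for the periovulatory list, and the macrophage list lies at 0.939.

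MHC class I and interferon-response genes were higher in the old section, whereas macrophage genes as a group were not. The macrophage list had 718.2 CPM in the old section and 765.2 in the young, a ratio of 0.939 (0.886 to 0.994), with none of 14 measured members at least 1.5-fold higher and 3 lower. Mertk, Tyrobp and Ms4a7 had ratios of 1.49, 1.46 and 1.38. Adgre1, which encodes F4/80, had 0.340 (0.183 to 0.588), Mrc1 had 0.516 (0.376 to 0.696) and Cd68 had 0.536 (0.347 to 0.804). The abundant Lyz2 and C1qa had 0.724 and 1.27. The list's side of 1 depended on the setting, at 1.07 with each bin weighted equally, 1.03 without Lyz2 and 1.19 without the young section's quadrant of high x and high y. The foamy or giant macrophage list had a ratio of 1.01 (0.973 to 1.06), and its members lay on both sides of 1. The list ratio was 1.79 without Lgals3, 0.622 without Spp1 and 0.887 without both. Spp1 was 41.1, Gpnmb, a lysosomal glycoprotein gene, was 4.68 (3.76 to 5.84) and Acp5 was 3.50 (2.11 to 5.89), while Cd36 was 0.273, Lgals3 0.428 and Plin2 0.515. The MHC class I list had a ratio of 1.53 (1.48 to 1.59), with 10 of 12 members at least 1.5-fold higher. The highest were Tap1 at 3.43, H2-Q6 at 3.09 and H2-K1 at 2.67, against 0.915 for Tap2, 1.07 for B2m and 1.56 for H2-D1. The MHC class II list had a ratio of 1.60 (1.48 to 1.74), but 2 of 6 measured members were at least 1.5-fold higher and 1 lower, with H2-Ab1 at 2.35, H2-Eb1 at 1.65, Cd74 at 1.39, H2-Aa at 1.24, H2-DMb1 at 0.859 and H2-DMa at 0.494. The interferon response list had a ratio of 1.47 (1.40 to 1.55), with 15 of 20 members at least 1.5-fold higher. The highest were Gbp2 at 5.87, Rsad2 at 3.29 and Gbp3 at 2.93, against 1.08 for Bst2 and 0.549 for Ifit2.

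Lymphoid genes were sparse in both sections. The B and plasma list had 145 counts in the old section and 55 in the young, a ratio of 5.79 (4.22 to 8.05). The immunoglobulin gene Igkc had a ratio of 18.9 (9.79 to 40.8) and Ighm of 1.56, and Igha was at least 16.8-fold higher against the floor on 23 old counts, with a lower 95% limit of 12.6. The T, NK and innate lymphoid list had 107 and 164 counts, a ratio of 1.43 (1.11 to 1.84), the dendritic list 1.33 (0.957 to 1.83), and the mast list 13.6 (7.13 to 28.5) on 68 and 11 counts. Neutrophil genes had 5 counts in each section, a ratio of 2.20 (0.505 to 9.54). The cytokine and chemokine list had a ratio of 0.857 (0.781 to 0.939), and of 1.04 without Mif, and Cxcl1, a neutrophil attractant, had 1 count in the old section against 74, a ratio of 0.0297 (0.00074 to 0.171). The complement list had a ratio of 0.443 (0.429 to 0.456), but its side of 1 depended on the setting, and C4b was at 12.1 and C3 at 5.43. The NF-kB and inflammasome list had a ratio of 1.30 (1.22 to 1.39), and the senescence-linked list of 2.03 (1.96 to 2.10). In the latter, 8 of 12 measured members were at least 1.5-fold higher and none lower by that size. Cdkn2a, which encodes p16, was 8.51 (3.83 to 21.4) on 31 old and 8 young counts, and Igfbp4 was 3.28. The most abundant members, Igfbp7 and Igfbp6, were 2.42 and 1.37, while Cdkn2c was 0.933 and Igfbp5 0.918. Igfbp7 alone held 3128 of the list's 5940 old counts, so the list ratio rested mainly on Igfbp genes.

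Within 1 region of alike expression, senescence-linked genes had the highest old/young ratio after the periovulatory list, and complement genes the lowest. Clustering 2233 bins of both sections gave 14 regions, and 92.9% of bins lay in regions in which at least 90% of bins came from 1 section. Only region 7, led by Ivns1abp, Tenm4 and Serpine2, had at least 20 bins in both sections, with 127 young and 31 old. With bins of 3 spacings, or with thinned bins, 2 regions did, of which the second is not described, and across settings 77.4% to 100% of bins lay in regions mostly of 1 section. There the senescence-linked list had a ratio of 4.004 (3.40 to 4.70) and the complement list of 0.228 (0.193 to 0.268). The theca list had a ratio of 0.308 (0.243 to 0.384) and the collagen and matrix list of 2.85 (2.60 to 3.12). The steroidogenesis list had a ratio of 2.36 (2.20 to 2.52), the luteal list of 2.27 (1.80 to 2.85) and the cholesterol synthesis list of 1.87 (1.51 to 2.30). The MHC class I list had a ratio of 1.75 (1.41 to 2.15), interferon response of 1.45 (1.09 to 1.90) and MHC class II of 1.44 (0.619 to 2.96). The macrophage list had a ratio of 1.62 (1.02 to 2.50), foamy or giant macrophage of 0.703 (0.512 to 0.946) and periovulatory of 6.50 (2.85 to 14.6), the last on 13 old and 15 young counts. The granulosa list is not given there because it holds Serpine2, nor the oocyte list, because clustering placed bins rich in oocyte genes in other regions. Clustering used the list genes too, and bins are not replicates, so these values describe the 2 libraries.

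Oocyte counts gathered in foci in both sections, and ovulation-induced genes gathered in patches in the old one. Groups of adjoining bins rich in oocyte counts numbered 15 in the young section and 2 in the old, holding 15208 and 490 oocyte-list counts. In bins thinned to 500 counts, Moran's I, which is near 0 for a list without spatial pattern, was 0.464 for the periovulatory list in the old section and -0.012 in the young, where only 14 counts remained and the value was 0.0236 with bins of 3 spacings. For the macrophage list it was 0.221 in the old and 0.167 in the young section, and for MHC class II 0.137 and 0.164. These values depended on bin size and thinning depth: 3 of 8 other values moved over 1.5-fold for macrophage and 7 of 8 for MHC class II. Proliferation genes were higher near the foci: in the ring of 0 to 5 bead spacings the list had 4486 CPM in the old section and 4538 in the young, against 966 and 1438 beyond 20 spacings. That ring also held 19548 oocyte-list CPM in the old section and 28326 in the young. Oocyte counts and those of surrounding cells were therefore not told apart there. Luteal genes were lower near the foci, at 392 and 226 CPM against 5016 and 4309 beyond 20 spacings.

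**Figure D3:**
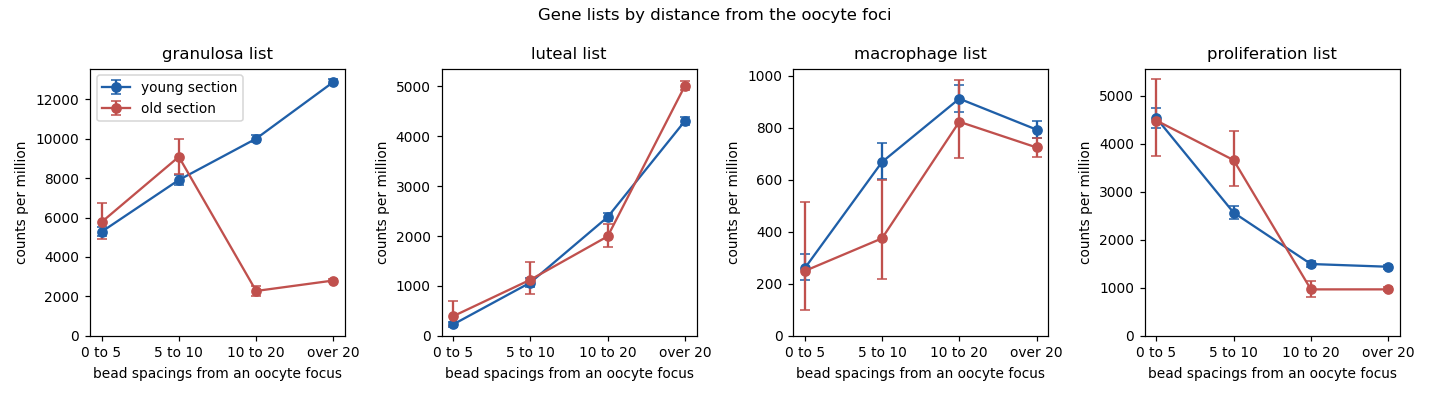
CPM of the granulosa, luteal, macrophage and proliferation lists by distance from the nearest oocyte focus in bead spacings, for the young (blue) and old (red) section, with 95% Poisson intervals for counting error. Granulosa counts in the old section reach 9084 at 5 to 10 spacings and 2804 beyond 20, while in the young section they reach 7907 and 12882.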

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

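The contrasts between parts of a section and the test of Spp1 by Adamts1 were chosen after the data were seen, while the test of Spp1 by macrophage content in the old section was set before its value was seen. Each difference between sections was not tested, because each age has 1 section. Most are contrasts within a section that went opposite ways in the young and the old section, by at least 1.5-fold and with counting intervals that exclude 1. Granulosa genes were flagged by this rule around oocyte foci. At 5 to 10 bead spacings the list was 0.614 times its level beyond 20 spacings in the young section and 3.24 times in the old. Its levels at 5 to 10 spacings were 7907 CPM in the young and 9084 in the old section. Beyond 20 spacings they were 12882 and 2804 CPM, so the opposite contrasts rested mainly on that part. The ring of 5 to 10 spacings also held 6564 oocyte-list CPM in the young section against 904 in the old. The old section had only 2 foci.

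Spp1 sat in different parts of the 2 sections. In the fifth of bins with the highest share of macrophage-list counts, Spp1 was 5.59 times its level in the other young bins (3.37 to 9.28, 68 counts in all) and 0.244 times in the old (0.178 to 0.328). In the fifth highest in the luteal list, it was 9.65 times in the young and 0.139 times in the old section. Macrophages as the main source of Spp1 counts in the old section are argued against by that 0.244. Spp1 was 11.8 times higher in the fifth of old bins highest in Adamts1 (10.1 to 13.9), so a candidate explanation is that Spp1 in the old section came from the part where ovulation-induced genes lay. An effect of age, of the animal or of the cycle stage stays open.

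Macrophage-associated genes also lay differently against the fifth of bins highest in the luteal list, but those bins were unlike in the 2 sections. Steroidogenesis genes outside the luteal list were there 1.25 times their level elsewhere in the young section and 2.56 times in the old. Cholesterol synthesis genes were 0.896 and 2.135 times, and collagen and matrix genes 2.96 and 0.932 times. A different placement of macrophages and a different kind of luteal-rich tissue cannot be told apart here. In the fifth of bins highest in the luteal list, the foamy or giant macrophage list was 4.31 times its level elsewhere in the young section and 0.427 times in the old. Without Lgals3 it was 2.23 and 0.334 times, without Spp1 4.28 and 0.637 times, and without both 2.15 and 0.567 times. For comparison, and outside that rule, the macrophage list was 2.23 times (2.09 to 2.39) and 0.807 times (0.706 to 0.920), and C1qa 2.60 times and 0.828 times (0.637 to 1.06). Gpnmb was 2.86 and 0.373 times, Cd36 2.14 and 0.327 times, and Lyz2 2.16 and 0.607 times.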

How the results depend on the processing

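The restriction to the densely covered part of the array and the removal of Spp1 were chosen after the data were seen. The former gave 0.0746 for oocyte, and the latter gave 0.622 for foamy or giant macrophage, or 0.887 without Lgals3 as well. Of 325 values of the list ratios under other settings, 206 stayed within the counting interval, 110 left it, and 9 crossed 1 from a ratio whose interval excluded 1. The 206 include the setting with all beads for each of the 36 lists, which equals the main ratio because no bead was left out. Equal weight per bin gave ratios of 0.135 for oocyte, 0.291 for granulosa, 0.241 for theca, 31.8 for periovulatory, 2.85 for cholesterol synthesis, 1.41 for luteal, 1.85 for collagen and matrix, 0.890 for foamy or giant macrophage and 1.07 for macrophage genes, the last 2 on the other side of 1. Leaving out each list's most abundant member gave 0.112 for oocyte, 0.300 for granulosa, 0.708 for theca, 8.32 for periovulatory, 2.90 for cholesterol synthesis, 1.71 for collagen and matrix, 1.03 for macrophage, which crossed 1, 1.79 for foamy or giant macrophage, 1.75 for MHC class II and 1.65 for interferon response. It also turned oviduct epithelium to 0.915, nerve and glia to 0.914, cytokine and chemokine to 1.04 and complement to 1.94. Beads with at least 200 counts gave 0.257 for granulosa, 0.265 for theca, 3.38 for cholesterol synthesis, 2.29 for collagen and matrix and 1.10 for foamy or giant macrophage.

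Leaving out 1 quadrant of 1 section gave 0.0504 to 0.114 for oocyte, 0.229 to 0.358 for granulosa, 0.226 to 0.285 for theca, 32.5 to 68.3 for periovulatory, 2.75 to 3.51 for cholesterol synthesis, 0.962 to 1.86 for luteal, 1.98 to 2.22 for collagen and matrix, 0.786 to 1.19 for macrophage, 0.755 to 1.16 for foamy or giant macrophage, 1.44 to 1.66 for MHC class I, 1.46 to 1.93 for MHC class II and 1.38 to 1.62 for interferon response. The stromal fibroblast list ran from 0.761 to 1.11. Within region 7, resolution 0.5 gave 2.40 for collagen and matrix and 2.12 for steroidogenesis, bins of 3 spacings gave 2.31, 2.64 and, for oocyte, 1.35, a value that clustering on oocyte genes leaves without meaning, and 0.165 for complement, and thinned bins gave 2.25 and 2.02; bins of 8 spacings left 3 old bins, too few to compare. Moran's I of the periovulatory list in the young section turned to 0.0236 with bins of 3 spacings. Moran's I moved over 1.5-fold in 7 of 8 other values for MHC class II and 3 of 8 for macrophage. A minimum of 200 counts kept 15 of the 24 named genes. Oocyte foci numbered 11 to 17 in the young section and 2 in the old under the other thresholds and bin sizes. The cause of these shifts was not tested. No paired analysis was possible because the sections share no animal and each age has 1. The neutrophil list had 5 counts in each section, so its ratio of 2.20 (0.505 to 9.54) excludes only differences beyond that wide interval.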

Other observations

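The comparison of bins by macrophage content, the test of the list's other members alone, the test of scaling and the clustering of thinned bins were chosen after the results were seen. Lysosome genes had a ratio of 1.87 (1.83 to 1.91), with Psap at 3.69, Ctsl at 3.09 and Npc2 at 2.55. Proliferation genes had a ratio of 0.581 (0.556 to 0.608), with Mcm2 at 0.161 and Ccnb1 at 0.222 but Rrm2 at 2.96. Antioxidant genes had 1.01 (0.983 to 1.04), with Srxn1 at 3.29 and Nqo1 at 0.244 (0.0474 to 0.793), and immediate early and heat shock genes 1.48 (1.39 to 1.57), with Ier3 at 5.57 and Fos at 0.266. Within region 7 these whole-section directions were not all kept. Proliferation genes stood there at 4061 CPM in the old and 3383 in the young section, with a ratio interval of 1.086 to 1.325. Immediate early and heat shock genes had a ratio of 0.598 (0.404 to 0.858) there, and lysosome genes of 1.03 (0.927 to 1.145). Antioxidant genes had a ratio of 0.931 (0.816 to 1.059) in that region. The adipocyte, nerve and glia, and oviduct epithelium lists had ratios of 0.945 (0.714 to 1.24), 2.32 (1.96 to 2.74) and 3.35 (2.63 to 4.28) on 2 measured members each; nerve and glia was 0.914 without Mbp, and oviduct epithelium 0.915 without Epcam. MHC class II genes lay with macrophage genes in both sections, at 5.85 times their level elsewhere in the fifth of young bins highest in the macrophage list and 4.70 times in the old.

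The elevation of periovulatory genes in the old section was set against 3 explanations. An effect of the whole library is argued against because the other members of the list were together 6.02 times higher (3.97 to 9.36) in the fifth of old bins highest in Adamts1 than in the other old bins. With 6 genes chosen for their high ratios (Prkg2, Edn2, Nts, Ptgs1, Apln and F3) beside Ptgs2, Tnfaip6 and Btc, the value was 10.8 (9.52 to 12.3). Scaling could not be decided by the median ratio over 8470 genes, which was 1.02. CPM divides each library by its own total, which keeps that median near 1 whatever the factor between the libraries. The value shows only that the periovulatory genes were higher relative to the typical gene. A hypothesis is that the old ovary was collected near ovulation. The 9 measured genes that the ovulatory surge induces had a median ratio of 2.60. Among them Snap25 was set at its floor ratio of 30.0, with Runx2 at 4.69, Rgcc at 4.53 and Cebpb at 2.41. Plat was at 0.865 and Phlda1 at 0.816. Cycle stage may therefore account for part of the difference between the sections, with age left open. The hypothesis is limited by Has2, Ptx3, Areg, Ereg and Pgr of the periovulatory list, which had fewer than 20 counts in each section.

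Bins grouped by section as well as by expression, with 92.9% in regions mostly of 1 section, while the oocyte genes Nlrp14 and H1f8 were among the leading genes of a region of 104 young and 7 old bins. A difference in depth is argued against, since 81.4% of bins still lay in regions mostly of 1 section after thinning to 500 counts. A few abundant noncoding, mitochondrial and ribosomal genes are argued against as well, since 93.5% did so without them. Age, animal, cycle stage and library preparation were not separable here, and no biological explanation was tested.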
